A study of Arabidopsis thaliana with 16 samples.

How the data were processed

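Binding of the transcription factors WRKY18, WRKY33 and WRKY40 to DNA was measured by ChIP-seq (chromatin immunoprecipitation followed by sequencing) in Arabidopsis thaliana seedlings. Per the labels, each factor carried an HA tag in a complementation line, and an anti-HA antibody was used for the precipitation. Seedlings were 12 days old and grown with 16 h of light and 8 h of dark. They were either untreated (0 h) or given 1 µM flg22, a peptide of bacterial flagellin that plants recognise, for 2 h. The labels' protocols give 2 g of seedlings per precipitation, 2 rounds of linear amplification of the precipitated DNA, and 7 to 20 M single-end reads of 100 bp per sample. The series holds 16 samples: 3 HA lines and untagged wild type (WT), at 2 times, with 2 biological replicates each, per the series' design text. The 4 WT samples have no peak list. Their labels name them as negative controls for peak calling, each for the 3 HA samples of the same time and replicate, so the 3 lines of 1 replicate and time shared 1 control.

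FastQC 0.11.2, cutadapt 1.2.1, Bowtie 0.12.7 and HOMER were used with genome build TAIR10, per the submitters' processing notes. The peak caller, its settings and its threshold are not given in the sources used here. Each of the 12 HA libraries has 1 peak list of its own, per the file headers, so replicates were not pooled by the authors. The deposited peak score is given for the HA library and for WT at each peak, and its scale is not stated in the headers. The lowest score in the 12 lists was 10.0. Tag counts per peak for the HA library and for WT are deposited as well. The deposited fold enrichments over WT are ratios, 1 of scores and 1 of tags, per the file headers. The score ratio lay within 1.37% of the HA score divided by the WT score, with WT scores under 1 set to 1. The lowest score ratio was 2.51. The lists also hold a −log10 q-value per peak, per the file headers, and its lowest value was 16.9. Each peak has a gene and a distance in bp to that gene's start, assigned by the authors. For 97.7% of the 2444 genes with at least 3 peaks, the distances led back to 1 start within 2 bp when measured from the peak's midpoint. From the peak's maximum this held for 0.0409%, so distances were read as midpoint distances.

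The peaks of each list are numbered in their names, nearly in score order, and some numbers are absent from the lists. Between 0 and 276 numbers were absent per list, including some near the top, and the rule behind this is not stated in the sources used here. A site missing from a list is therefore not evidence that the factor was not bound there. No read totals per library were used, so depth is known only as the range of reads above. Depth per peak was read from the tags, whose median per list lay between 141 and 678. Intervals given below cover counting error only.

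The analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Every peak in the lists was kept, 16600 in all. Peaks of both replicates of a line were merged where they overlapped by at least 1 bp, and a merged site was reproducible when it held a peak of each replicate. Chance was estimated from 1000 random circular shifts of the replicate 2 list within each chromosome. Such shifts do not keep the position of peaks relative to genes. Sites of the 3 lines were then merged in the same way, with 1000 shifts of the site lists of both other lines. Because lines of 1 replicate shared a WT control, overlaps between lines were also computed between lists of different replicates, with each list limited to its 1653 best-scoring peaks, the length of the shortest 2 h list. A site had no 0 h peak when it overlapped no peak of either 0 h list of its line. A site of 1 factor only overlapped no 2 h peak of the other lines in any list. Site strength was the mean rank percentile by score in both lists, with low percentiles for strong sites. Promoter shares came from the distances assigned by the authors. Coordinates are 1-based in build TAIR10, as in the lists.

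Target genes were those that the authors assigned to the peaks of reproducible sites. Gene symbols and the order of genes along chromosomes came from a RefSeq gene table of assembly TAIR10.1, from which no coordinates were used. It held 4217 of the 4317 target loci of all lists, and all 308 members of the fixed gene lists. There were 16 gene lists: 14 immune and stress groups and 2 control groups (photosynthesis genes and highly expressed housekeeping genes). The members were written from general knowledge of the field, and 6 belong to more than 1 list. Each list was compared with all 37899 loci of chromosomes 1 to 5 by Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over the 16 lists of a line and a threshold of 0.05. The share of other genes that were targets served as background. Targets were also rotated 1000 times along the gene order of each chromosome, which keeps neighbouring targets together. A gene with a long upstream region takes more peaks by chance, and neither the test nor the rotation corrects for this.

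Named genes followed a rule: the 10 best-ranked reproducible 2 h sites per line, up to 4 members per gene list (those bound by all lines first), the 5 best-ranked sites of 1 factor only and the 5 best-ranked reproducible 0 h sites per line, and WRKY18, WRKY33, WRKY40 and WRKY60. Genes outside the rule are said to be so where they appear. The groups, planned tests, gene lists, naming rule and the alternatives planned were fixed before the data were examined. Not in this plan were the comparison of the WRKY18 log2 ratio with the other lines and the comparisons between lines of promoter shares and of shares of sites of 1 factor only.

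Numbers of peaks at 2 h and 0 h were compared by an exact permutation test (two-sided) of the mean log2 number per library, with times permuted within each line over all 216 arrangements. Within 1 line, 2 libraries against 2 cannot give a p below 0.333, so the values per line carry no test. Shares of promoter sites and of sites of 1 factor only were compared between lines by Fisher's exact test with Benjamini-Hochberg adjustment over the 3 pairs of lines. Sites are not independent replicates, and such p-values describe sites within these libraries. Share intervals are exact 95% (Clopper-Pearson). The labels link libraries by replicate number through their WT control. The planned test of peak numbers had no replicate block, and a test permuting times within line and replicate was run as an alternative. At peak maxima found at the same position in 2 of the 2 h lists, the WT score had a Spearman correlation across peaks of 0.973 to 1.0 in the 6 pairs of lists of 1 replicate. It was −0.0667 to 0.809 in the 9 pairs of different replicates. Replicate 2 had the longer list in 5 of the 6 groups.

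The scripts were tested on simulated data. Of 1000 planted sites, placed with random peaks in lists of the real lengths, 1002 reproducible sites were found for WRKY18, 1007 for WRKY33 and 1009 for WRKY40. With lists of which 40% of members were planted as targets, 81.0% were called for WRKY18, 87.0% for WRKY33 and 83.5% for WRKY40. Of lists with nothing planted, 1.25%, 0.5% and 1.25% were called. For the peak number, 6.5% of 200 simulated sets without a time effect gave a p below the threshold. The test of gene families by symbol, described under the other observations, called 94.0% of 50 planted families and 0 others.

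Alternatives covered the overlap rule, the better-scoring 50% of each list, each replicate left out, each line left out, the replicate block, the linear scale, the distance upstream and the background of genes. Added after seeing the data were nuclear chromosomes only, WRKY18-HA 0 h replicate 2 left out, equal list lengths, targets within 1000 bp of a start, and rotated targets. The planned search for the W-box, the short DNA motif that WRKY factors recognise, was not run because no genome sequence was used here. For the same reason, promoter shares have no chance level, and targets were not reassigned by gene body.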

Results

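DNA binding of WRKY18, WRKY33 and WRKY40 was measured in Arabidopsis seedlings before and 2 h after flg22, a bacterial peptide that sets off pattern-triggered immunity. These factors belong to a plant family whose members recognise short motifs in the promoters of defence genes. Each line expressed 1 factor with an HA tag, and each group of 1 line at 1 time had 2 biological replicates, which gives 12 libraries with a peak list. Peaks were called by the authors in each library against the WT control of the same time and replicate. The lists held 16600 peaks. The median number of tags per peak was 141 to 528 in the 0 h lists and 222 to 678 in the 2 h lists. Libraries had 7 to 20 M reads per the labels' protocols, and the total of each library is not known here.

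The first question was how the peaks of each factor differed between untreated seedlings and those given flg22 for 2 h. After 2 h, peaks of WRKY33 and WRKY40 rose from 44 or fewer per list to 1653 or more, reaching genes such as MLO6 and NILR1 for WRKY33 and BZIP60 and NADK1 for WRKY40. WRKY18 was already found at many places in untreated seedlings, among them its own locus, ERF-1 and KCS12, and had more peaks after flg22. The WRKY18-HA lists held 260 and 1843 peaks at 0 h (replicates 1 and 2) and 1801 and 2994 at 2 h. The WRKY33-HA lists held 9 and 44 peaks at 0 h, against 1653 and 2656 at 2 h. The WRKY40-HA lists held 31 and 20 peaks at 0 h, against 2017 and 3272 at 2 h. The mean number at 2 h was 2398 ± 844 (SD, n = 2) for WRKY18, 2155 ± 709 for WRKY33 and 2645 ± 887 for WRKY40. At 0 h the means were 1052 ± 1119, 26.5 ± 24.7 and 25.5 ± 7.78. Over the 3 lines, the mean log2 ratio of 2 h to 0 h was 5.05, a 33.2-fold rise, with a higher number at 2 h in 6 of 6 pairs of libraries (exact permutation test, two-sided p = 0.0185, where the smallest p possible was 0.00926). The rise was 3.35-fold for WRKY18 (log2 1.75 ± 1.48, SD, n = 2), 105-fold for WRKY33 (6.72 ± 1.14) and 103-fold for WRKY40 (6.69 ± 0.94). On nuclear chromosomes alone the rise was 3.37-fold, 112-fold and 287-fold (log2 8.17 ± 1.15 for WRKY40), since 27 of the 31 peaks of WRKY40-HA 0 h replicate 1 lay on the mitochondrial chromosome. The WRKY18 log2 ratio minus that of the other lines was −4.96 (exact permutation p = 0.0667, the smallest that 15 arrangements can give). This comparison was not planned. A number of peaks depends on depth and on the authors' threshold as well as on binding. No untreated seedlings were sampled at 2 h, so flg22 cannot be told apart from time or handling. The 0 h and 2 h lists were also called against different WT controls.

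**Figure D1:**
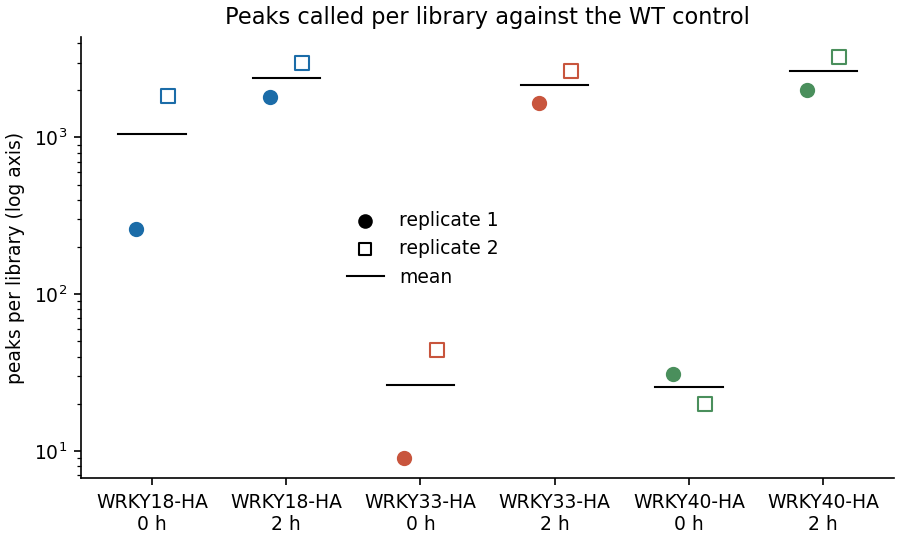
Number of peaks per library (log axis) for each HA line at 0 h and 2 h, with replicate 1 as filled circles, replicate 2 as open squares and the mean of 2 as a line. All 6 libraries at 2 h hold 1653 or more peaks, while at 0 h only WRKY18-HA exceeds 44.

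The strongest sites after flg22 included a few known defence genes beside genes of other or unknown function. PEN3, which encodes an ABC transporter that exports defence compounds, was among the 10 best sites of all 3 lines. WRKY18 and WRKY40 had most of their best sites in common: besides PEN3, these were LPA2, BZIP60 (a regulator of the unfolded protein response), CYP81D8, NADK1 (an NAD kinase), AT1G17147 (a VQ-motif protein), AT1G65500 and AT1G62301. Their sites assigned to LPA2 were centred 1647 and 1677 bp downstream of its start, not in its promoter. WRKY33 had a different top list, led by AT1G64405, AT1G14730 (a cytochrome b561 protein), MLO6 (a membrane protein of powdery mildew susceptibility) and PEN3. The PEN3 site of WRKY40 spanned chromosome 1 positions 22033252 to 22034758, in the promoter. It scored 136 and 153 in replicates 1 and 2, with tags 26.7-fold and 32.4-fold over WT. The WRKY18 site at PEN3 scored 105 and 110, and the WRKY33 site 56.8 and 77.8. Scores cannot be compared directly between lines, because their ranges differ. The highest 2 h scores were 72.3 and 97.1 for WRKY33, 262 and 209 for WRKY18, and 195 and 193 for WRKY40. By rank within the lists, PEN3 was 4 and 5 for WRKY33, 5 and 12 for WRKY18, and 2 and 4 for WRKY40. At BZIP60 (chromosome 1, from 16137457 to 16138376), WRKY40 scored 119 and 113, and WRKY18 scored 130 and 83.4. The MLO6 site of WRKY33 (chromosome 1, from 22711920 to 22712461) lay at the start of the gene and scored 49.4 and 83.1, where WRKY18 scored 12.2 and 10.3 and WRKY40 14.4 and 12.8. AT1G64405 scored 72.3 and 83.1 with WRKY33, and AT1G14730 scored 72.2 and 97.1. The remaining best sites of WRKY33 lay at AT3G48650, the receptor kinase gene NILR1 (AT1G74360), AT3G49610, AT5G44575, AT2G02210 and AT5G46295. The strongest site of WRKY18 was its own locus, followed by FH4 (a formin, scores 128 and 134). WRKY40 also had AT4G08850, a leucine-rich repeat protein gene, and AT1G65490 among its best. FH4 was listed in WRKY40-HA replicate 2 and not in replicate 1, so it did not count as a reproducible WRKY40 site.

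Reproducible sites, found in both replicates, numbered 1450 for WRKY18, 1237 for WRKY33 and 1658 for WRKY40 at 2 h. Randomly shifted lists gave 57.2, 39.8 and 65.2 on average, and at most 214, 234 and 287 in 1000 shifts. Replicate 1 peaks were found in replicate 2 in 82.8%, 75.5% and 85.4% of cases. In the longer replicate 2 lists, the tercile with the best scores was found in replicate 1 in 80.8% of cases for WRKY18, 78.4% for WRKY33 and 85.0% for WRKY40, against 23.8%, 23.3% and 21.7% in the weakest tercile. The authors' gene assignments gave 1343 target genes for WRKY18, 1174 for WRKY33 and 1532 for WRKY40.

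The next question was which sites were bound before flg22. Almost no WRKY33 and WRKY40 sites had a peak in untreated seedlings, with PEN3 an exception for WRKY33. WRKY18 had reproducible 0 h sites at its own locus, PUP18 (a purine permease), ERF-1 (an ethylene response factor), KCS12 (a fatty acid elongase) and the formamidase gene AT4G37550. Of the 2 h sites, 533 of 1450 (36.8%, 95% interval 34.3 to 39.3) had no 0 h peak for WRKY18. The share was 1221 of 1237 (98.7%, 97.9 to 99.3) for WRKY33 and 1643 of 1658 (99.1%, 98.5 to 99.5) for WRKY40. The WRKY18 share rested on replicate 2: without that 0 h library, 84.6% of its sites had no 0 h peak. A 0 h peak in both libraries was found at 196 WRKY18 sites. With 0 h replicate 1 alone, 223 of the WRKY18 sites (15.4%) had a 0 h peak, against 7 (0.566%) for WRKY33 and 0 for WRKY40, whose 0 h lists of that replicate held 9 and 31 peaks and so limit these shares. With 0 h replicate 2 alone the shares were 61.3%, 0.970% and 0.905%. Stronger WRKY18 sites had a 0 h peak more often: 84.1% in the strongest tercile of 2 h sites, 63.4% in the middle and 42.2% in the weakest.

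The reproducible 0 h sites numbered 214 for WRKY18, 3 for WRKY33 and 1 for WRKY40, and 195 of the 214 WRKY18 sites lay in reproducible 2 h sites. At PUP18, WRKY18 scored 71.5 and 63.6 at 0 h. ERF-1 scored 44.3 and 59.2, KCS12 46.2 and 50.4, and AT4G37550 42.8 and 55.8. The WRKY33 sites lay at PEN3 (13.7 and 17.6), AT1G78310, another VQ-motif protein gene (12.1 and 11.2), and PUP18 (12.1 and 10.5). The WRKY40 site, on chromosome 1 from 30379191 to 30380743, lay between AT1G80831 and WRKY40 and scored 22.7 and 28.3. The region at PUP18 was not listed in WRKY18-HA 2 h replicate 2. A site without a 0 h peak was below the authors' threshold there or absent from the list, and was not shown to be unbound.

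Binding after flg22 was then compared between the factors. A core of sites was bound by all 3, including PEN3, BZIP60, LPA2, CYP81D8, MLO6 and NILR1. WRKY18 and WRKY40, which belong to the same subgroup of the family, shared most of their sites, NADK1 among them. WRKY33, from another group, shared about as many sites with each of them and had many apart from both. Of 2366 merged sites, 584 (24.7%) were bound by all 3 factors, against a mean of 0.859 and a highest count of 7 in shifted lists. The shifts keep neither the position of sites near genes nor the overlap between pairs of lines, so this is a low bar. A further 648 were bound by WRKY18 and WRKY40, 84 by WRKY33 and WRKY40 and 53 by WRKY18 and WRKY33. Of the WRKY18 sites, 85.2% (83.3 to 87.0) overlapped a WRKY40 site and 43.9% (41.4 to 46.5) a WRKY33 site. As target genes, WRKY18 and WRKY40 shared 1158, where 54.3 would be shared if targets were drawn independently. WRKY33 shared 626 with WRKY18 and 678 with WRKY40, where 41.6 and 47.5 would be. Fisher's exact p was printed as 0 for all 3 pairs, too small for the software to represent, with odds ratios of 606, 57.4 and 57.4. All 3 factors shared 581 target genes of 2168 bound by any.

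Sharing was stronger between lists of 1 replicate, which were called against the same WT control. The control and the replicate cannot be told apart here. At equal list lengths, 82.9% of peaks (81.2 to 84.0 over 4 values) were shared between WRKY18 and WRKY40 lists of 1 replicate. Between lists of different replicates, which had different controls, the share was 66.2% (65.1 to 67.7). Replicates of WRKY18 shared 65.0% and 66.5%, those of WRKY40 67.5% and 69.9%, and those of WRKY33 60.7% and 61.0%, so the mean between WRKY18 and WRKY40 lay within the WRKY18 values and below the WRKY40 values. WRKY33 lists shared 43.6% with WRKY18 and 43.9% with WRKY40 across replicates, and 49.5% and 49.9% within them. Stronger sites were more often shared by all 3: among WRKY33 sites, 63.7% in the strongest tercile and 45.6% in the middle, with the lowest share in the weakest. The shares were 61.2%, 36.4% and 23.2% for WRKY18, and 59.0%, 31.8% and 15.6% for WRKY40.

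**Figure D2:**
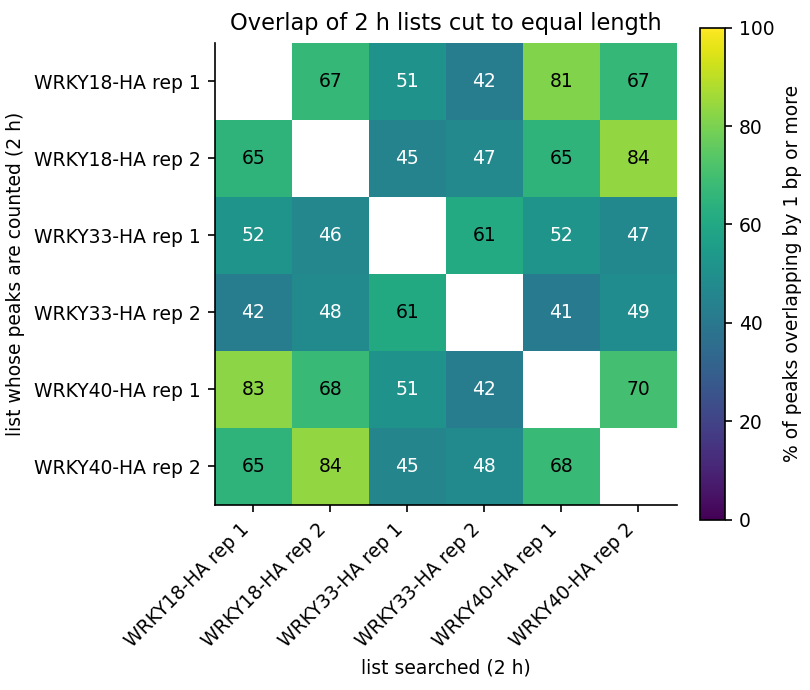
Percent of the peaks of each 2 h list (vertical axis) that overlap a peak of another 2 h list (horizontal axis) by 1 bp or more, with each list limited to its 1653 best-scoring peaks. WRKY18-HA and WRKY40-HA lists share a mean of 82.9% of peaks within a replicate and 66.2% across replicates, while lists of 1 line share 60.7% to 69.9%.

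**Figure D3:**
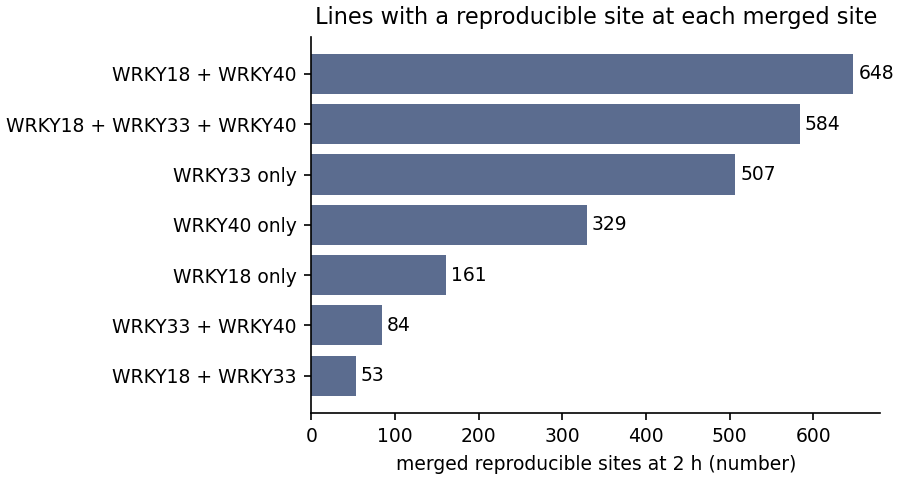
Number of merged reproducible 2 h sites (horizontal axis) by the set of lines with a reproducible site there. WRKY18 with WRKY40 (648) and all 3 lines (584) are the largest sets, followed by WRKY33 alone (507).

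Which immune pathways the sites lay near was asked with 16 gene lists. All 3 factors bound near genes of camalexin synthesis (PAD3, CYP79B2, GSTF6), indole glucosinolate defence (MYB51, PEN2, CYP81F2, IGMT2), penetration resistance and secretion (PEN3, MLO6, MLO12, SNAP33) and the perception of microbes and damage (CERK1, PEPR1, NILR1, PUB12). Genes were counted by the authors' assignment, so a shared gene need not be a shared site. At MYB51, the best WRKY18 site lay at 1437 bp from the start (scores 29.4 and 10.7). Those of WRKY33 and WRKY40 lay at −877 and −880 bp. At PEN2 the best sites lay at −1888, −1144 and −46 bp for WRKY18, WRKY33 and WRKY40. The danger peptide genes PROPEP2 and PROPEP3 were bound by all 3, as were many other WRKY genes, such as WRKY15, WRKY41 and WRKY71. None of the genes in the photosynthesis control list was a target. Of all other genes, 3.49% were targets of WRKY18, 3.05% of WRKY33 and 3.98% of WRKY40. Of 66 WRKY genes, WRKY18 bound 22, WRKY33 21 and WRKY40 27 (Fisher's exact test, adjusted p = 6.80e-15, 6.52e-15 and 1.64e-19). Of 9 genes in the list of penetration resistance and secretion, 6, 7 and 6 were bound (exact adjusted p = 4.80e-07, 7.34e-09 and 1.31e-06), and of 28 pattern receptor genes 10, 10 and 11 (1.18e-07, 3.30e-08 and 2.76e-08). The list of penetration resistance and secretion also holds MLO genes, of which MLO6 was described above under powdery mildew susceptibility. Of 7 camalexin genes, 3, 4 and 5 were bound (exact adjusted p = 0.00248, 6.80e-05 and 5.61e-06), and of 10 indole glucosinolate genes 5, 6 and 5 (2.75e-05, 5.27e-07 and 3.65e-05). Of 9 early flg22 marker genes, 6, 6 and 5 were bound, among them WRKY53, WRKY30 and WRKY29. The 6 genes that belong to more than 1 list are all in the marker list, WRKY53, WRKY30 and WRKY29 included. Its result therefore repeats part of the other lists. Of 4 PROPEP genes, each factor bound 2. In all, 12 lists were called for WRKY18, 12 for WRKY33 and 11 for WRKY40. The photosynthesis list had 0 of 23 genes bound by each factor, and the housekeeping list 0, 0 and 1 (ACT7) of 15.

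Hormone and kinase pathways were bound as well. Near ethylene genes, all 3 factors bound at ACS6 and ACS8, which make the ethylene precursor, and EBF2, which restrains the response. At ACS6, WRKY40 scored 77.2 and 115, WRKY18 56.1 and 74.9, and WRKY33 32.5 and 29.5, on score ranges that differ between lines. Of 23 ethylene genes, WRKY18 bound 12, WRKY33 6 and WRKY40 14. Targets of WRKY18 or WRKY40 without WRKY33 held 8 ethylene genes and targets of WRKY33 alone held 0, a difference that was not established (Fisher's exact p = 0.0634, adjusted p = 1). Of 24 salicylic acid genes, 7, 5 and 8 were bound, including PBS3, EDS5 and ALD1 by all 3 factors and NIMIN1 by WRKY18 and WRKY40. At ALD1, which acts in systemic resistance, WRKY40 scored 21.7 and 93.6, and WRKY18 38.8 and 82.0. Of 16 MAP kinase genes, 4, 6 and 7 were bound: MAPKKK5 and MPK11 by all 3, MKK9 by WRKY18 and WRKY40, and MKP1 by WRKY33 and WRKY40. Of 15 other stress transcription factor genes, 6, 4 and 6 were bound, including MYB15, ZAT10 and NAC055 by all 3 and SIB2 by WRKY18 and WRKY40. With peaks limited to 1000 bp from a start, this last list was not called in any line (exact test, adjusted p = 0.426, 0.0602 and 0.348, the highest of the alternatives run), and the ethylene list was not called for WRKY33 (0.470, also the highest). Limited to the better-scoring 50% of each list, the MAP kinase and salicylic acid lists were not called for WRKY33 (0.292 and 0.0752, the highest of the alternatives run).

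Jasmonate, abscisic acid and calcium genes had few targets, and their lists were called in 1 line or none. Of 23 jasmonate genes, 2, 3 and 3 were bound, with LOX4 bound by all 3, LOX3 by WRKY18 and WRKY40, AOC3 by WRKY33 and WRKY40, and JAZ6 by WRKY33 with scores of 26.1 and 55.7. The list was called for WRKY33 only (exact test, adjusted p = 0.0441), and not with protein-coding genes as background (0.0884, and 0.000428 to 0.470 over the alternatives). Of 21 abscisic acid genes, 3, 1 and 3 were bound: CYP707A3, which breaks down abscisic acid, by all 3, PYL4 by WRKY18 and WRKY40, NCED3 by WRKY18 and MYB2 by WRKY40. This list was called for WRKY18 only (exact test, adjusted p = 0.0489), and not with protein-coding genes as background (0.0989, and 0.000373 to 0.471 over the alternatives). Whether these shares differ between factors is not shown, since no list differed between targets of WRKY33 alone and targets of the others. Of 21 calcium and reactive oxygen genes, 2, 2 and 3 were bound, and the list was not called: CML9 by all 3, CPK11 by WRKY18 and WRKY40, RBOHF by WRKY33 and RBOHD by WRKY40. With single lists in place of reproducible sites, the calcium list was called in 5 of 6 cases.

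**Figure D4:**
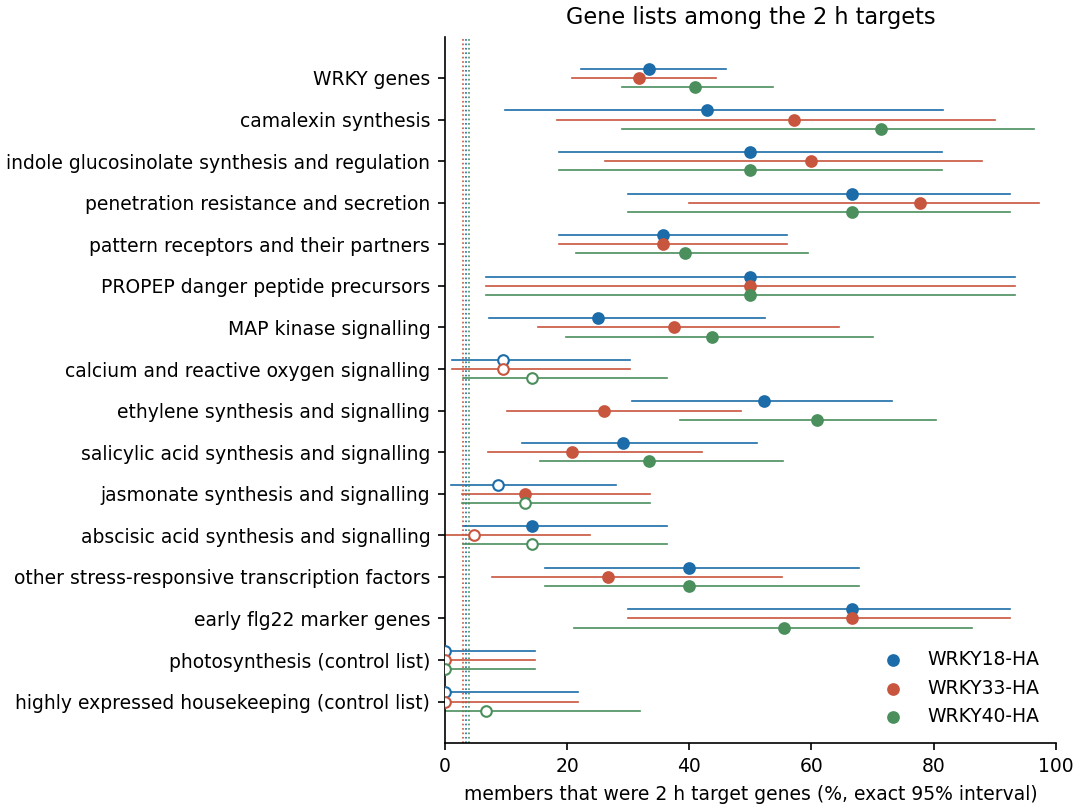
Percent of the members of each of 16 gene lists that were 2 h targets (horizontal axis, points with exact 95% intervals) of WRKY18-HA, WRKY33-HA and WRKY40-HA, with filled points for lists called at an adjusted p under 0.05 and dotted lines for the share of all other genes (3.49%, 3.05% and 3.98%). The photosynthesis and housekeeping control lists lie at 0 to 6.67%, and the list of penetration resistance and secretion lies at 66.7% to 77.8%.

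Sites with no peak of another factor in any list were rarer for WRKY18 and WRKY40 than for WRKY33. The strongest sites found with WRKY33 alone lay at AT2G27389, AT5G44565, AT2G44500, AT2G42060 (a C1-domain protein gene) and the kinase gene MPK5. The few WRKY18 sites included AGO1, which acts in RNA silencing, and MYB17, and those of WRKY40 included NAGS2 and EDA9, genes of amino acid synthesis. Sites with no 2 h peak of another line in any list numbered 239 for WRKY33 (19.3% of its sites, 17.2 to 21.6). WRKY18 had 20 (1.38%, 0.844 to 2.12) and WRKY40 had 40 (2.41%, 1.73 to 3.27). When only reproducible sites of the other lines excluded a site, the counts were 161 for WRKY18, 507 for WRKY33 and 329 for WRKY40. The WRKY33 share was higher than that of WRKY18 (Fisher's exact test, adjusted p = 1.07e-61) and of WRKY40 (1.24e-54). WRKY40 lay above WRKY18 by less (0.0373). These shares depend on the lines compared, since WRKY18 and WRKY40 had most sites in common and so exclude each other's sites. AT2G27389 (chromosome 2, from 11719559 to 11720488) scored 35.0 and 35.1 with WRKY33. AT5G44565 scored 30.8 and 30.2, AT2G44500 25.7 and 36.9, AT2G42060 30.1 and 27.3, and MPK5 27.9 and 26.8. The other WRKY18 sites named by the rule lay at AT3G50651, AT4G00755 and AT4G16260, and the 5 scored 11.6 to 22.8. The other WRKY40 sites lay at AT1G32928, HAP8 and AT5G35735. Of the WRKY33 sites, 42 were in the strongest tercile of its sites, against 0 for WRKY18 and WRKY40. No gene list was enriched among these targets (Fisher's exact test, lowest adjusted p = 0.351, with 1 list at an unadjusted p of 0.0219, where WRKY40 alone bound RBOHD). A site missing from another line's list was below the threshold there or absent from the list used here.

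The factors were also compared at the genes of the WRKY factors themselves. WRKY18 bound upstream of its own gene and of WRKY40 and WRKY60 at both times (WRKY60 at 0 h in 1 replicate). WRKY40 bound at all 3 genes after flg22, and at 0 h upstream of its own gene and, in replicate 2, at WRKY18. WRKY33 bound its own promoter after flg22, where WRKY40 was found as well. The WRKY18 locus was the strongest peak in all 4 WRKY18-HA lists, with scores of 238 and 272 at 0 h and 262 and 209 at 2 h. It spanned 4480 to 5116 bp (chromosome 4, from 15378842 to 15383957 in 2 h replicate 1). WRKY40 bound there with ranks 34 and 9 at 2 h, over 2197 and 2454 bp, and with 2 peaks at 0 h (ranks 3 and 18 of 20 in replicate 2), and WRKY33 with ranks 624 and 1420 at 2 h. At the WRKY33 promoter (chromosome 2, from 16107695 to 16108427 in 2 h replicate 1), WRKY33 ranked 66 and 239, WRKY40 870 and 2229, and WRKY18 870 in replicate 1 only. No peak was listed at WRKY33 at 0 h. The WRKY40 promoter was bound by WRKY40 at 2 h with ranks 41 and 75. A second region farther upstream was rank 1 in WRKY40-HA 2 h replicate 1, with a score of 195, and was not listed in replicate 2. WRKY40 ranked 3 and 2 there at 0 h, and WRKY18 15 and 44 at 0 h and 58 and 18 at 2 h. WRKY33 had peaks of rank 571 and 651 in this region in 2 h replicate 1 only. At WRKY60, WRKY18 ranked 15 and 45 at 2 h and 8 in 0 h replicate 1, WRKY40 ranked 40 and 114, and WRKY33 782 in replicate 1. A tagged transgene adds copies of its own locus, so a peak at a line's own gene can come in part from copy number.

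**Figure D5:**
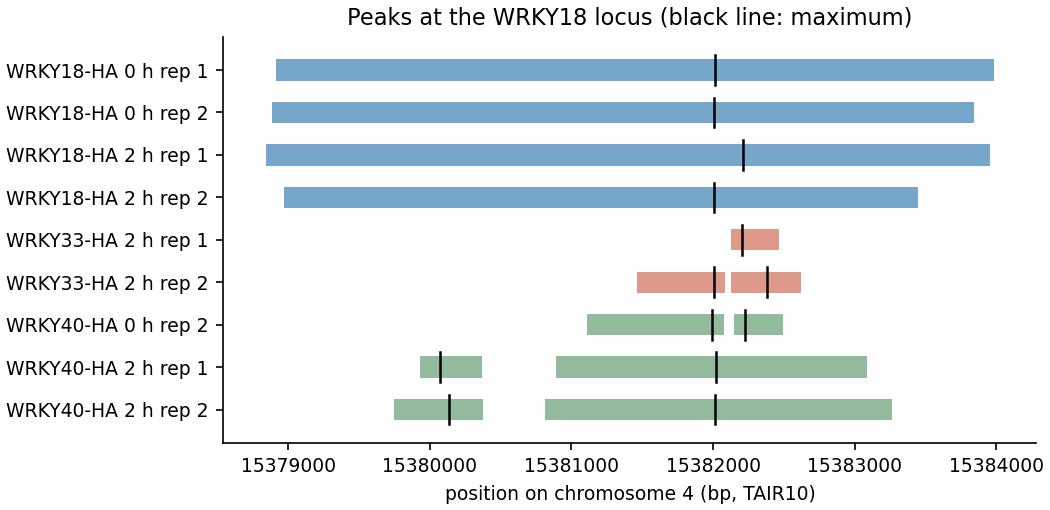
Peaks at the WRKY18 locus in each list that has one (vertical axis) by position on chromosome 4 in bp (TAIR10), with bars for peaks and black lines for their maxima. WRKY18-HA peaks span 4480 to 5116 bp at both times, and the WRKY40-HA 2 h peaks around the same maxima span 2197 and 2454 bp.

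Many sites lay close upstream of genes, as at PEN3, where the WRKY40 site was centred at −501 bp from the start, and BZIP60 (−448 bp). Others lay farther off, such as WRKY18's site at NADK1 and its site at KCS12 in untreated seedlings. Of the 2 h sites, 51.0% (48.4 to 53.6) of WRKY18, 57.0% (54.2 to 59.8) of WRKY33 and 49.8% (47.4 to 52.3) of WRKY40 were centred within 1000 bp upstream of a gene's start. WRKY33 had the higher share against WRKY18 (Fisher's exact test, adjusted p = 0.00285) and WRKY40 (0.00043), while WRKY18 and WRKY40 were not shown to differ (0.541). The median position was −338.5 bp for WRKY18 and −345 bp for WRKY33 and WRKY40. Sites more than 2000 bp from a start made up 17.4%, 15.9% and 17.7%.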

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

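The share of sites with a 0 h peak per line was planned; its comparison between lines and the tests of explanations in this part were chosen after the results were seen.

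The share of 2 h sites with a 0 h peak was 61.9 percentage points higher for WRKY18 than for WRKY33, and 62.3 points higher than for WRKY40. This difference between groups follows in large part from the lengths of the 0 h lists, 44 peaks or fewer for the other lines, and within WRKY18 the share was 15.4% with 0 h replicate 1 and 61.3% with replicate 2, so a test over sites adds nothing and the difference was not tested against the spread between libraries. Peaks on the mitochondrial chromosome, outside the comparisons of nuclear binding, were listed in 3 libraries: 27 in WRKY40-HA 0 h replicate 1, 2 in WRKY18-HA 0 h replicate 1 and 1 in WRKY33-HA 0 h replicate 1. The 27 had a median of 632 tags against 304 in WT, a median tag ratio of 1.81 and a highest ratio of 3.07. All 3 libraries were called against the same WT control, and no explanation was tested.

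The difference in 0 h binding rests mostly on WRKY18-HA 0 h replicate 2, with 1843 peaks against 260 in replicate 1. The WT control shared by that replicate is argued against as the source, since the longer of the other lists called against it has 44 peaks. Whether it is a mislabelled 2 h library of the line cannot be settled. At equal list lengths 51.8% of the 2 h replicate 1 peaks were found in it. The lowest share between 2 h lists of different replicates of 1 line, or of WRKY18-HA and WRKY40-HA, was higher (60.7%). Those lists were called against 2 h controls and this one against a 0 h control, so the shares are not fully comparable. Of its peaks, 65.6% were found in 2 h replicate 2, against 65.0% and 66.5% between the 2 h replicates of the line. An admixture of 2 h replicate 2 stays open as well. A lower sensitivity of replicate 1 stays open too: with lists of 260 peaks each, 46.2% of the 0 h replicate 1 peaks were found in replicate 2, below the 57.3 to 57.7% between the 2 h replicates of the line, and a noisier replicate 1 or different sites would both lower this share. In the full lists, 83.5% of the replicate 1 peaks lay in replicate 2, and 93.5% and 90.0% in the 2 h lists of the line. Most replicate 1 peaks were thus not sites of that library alone, although longer lists take up more peaks. Binding of WRKY18 before flg22 stays open as the biological explanation; both 0 h libraries of the line show it at WRKY18, ERF-1 and KCS12, and it was not tested apart from the expression of the transgene.

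At the WRKY18 locus, the strongest peak of every WRKY18-HA list, extra copies of the transgene without any binding are argued against: each maximum lies within 7 bp of a maximum of another line. Binding read over extra copies stays open, because the narrowest WRKY18-HA peak there (4480 bp) is wider than the widest of another line (2454 bp), and the design cannot separate copy number from stronger binding of WRKY18 to its own gene.

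WRKY33 had more sites of its own than the other factors, such as AT2G27389 and MPK5. The counts depend on the lines compared, because any peak of another line excludes a site. WRKY18 and WRKY40 exclude most of each other's sites, since 85.2% of WRKY18 sites overlapped a WRKY40 site. Without WRKY33, 648 merged sites were bound by WRKY18 and WRKY40 together, against 507 by WRKY33 alone. Different list lengths are argued against, since at equal lengths WRKY33 had 292 such sites and the next line 21. Peak numbers absent from the other lists stay open, since the 2 h lists of the other 2 lines lack 538 numbers, more than the 239 such sites, and where these peaks lay is not known. The authors' score limit stays open as well, because these sites are weaker than WRKY33 sites in general (median rank percentile 51.7 against 38.0) and values under the limit were not analysed here. A difference in the sites that WRKY33 recognises may also account for the pattern, and was not tested.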

How the results depend on the processing

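Nuclear chromosomes only, WRKY18-HA 0 h replicate 2 left out, equal list lengths, targets within 1000 bp of a start and rotated targets were chosen after seeing the data; the other alternatives were planned. No result reversed, although counts and shares carry no direction that could reverse. Of the main results under an alternative, 54 were scored as unchanged, 42 as moved and 5 lost the threshold. Shares were scored against their interval for counting error. Counts have no spread here and were scored by their ratio to the main count. For reproducible WRKY18 sites, 1801 against 1450 was scored as unchanged and 2994 as moved. For counts, unchanged therefore does not mean within a spread between libraries.

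The rise in peak number kept its direction under every alternative run. Read as a paired design with replicate as block, its exact p was 0.0312. It stayed past the threshold with a common score minimum (log2 5.95), on the linear scale (2031 peaks), on nuclear chromosomes (5.57) and without WRKY18-HA 0 h replicate 2 (5.52). Of the values per line, that of WRKY40 moved on nuclear chromosomes (log2 8.17), because most peaks of its 0 h replicate 1 are mitochondrial. Without 1 replicate the pooled value was 4.66 to 5.45, where the smallest exact p possible is 0.25. Without the WRKY18 line it was 6.70 (exact p 0.0556, the smallest possible), without WRKY33 4.22 and without WRKY40 4.23 (exact p 0.111 for both); fewer libraries were tested in each.

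With the better-scoring 50% of each list, reproducible sites fell to 696, 594 and 801 for WRKY18, WRKY33 and WRKY40 and sites of all 3 to 239, because fewer peaks were used. With 1 replicate the counts were 1801 to 2994, 1653 to 2656 and 2017 to 3272, and 808 to 1376 for all 3. Stricter overlap rules and equal lengths left the sites of all 3 at 419 to 525.

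The WRKY18 share of sites without a 0 h peak varied most: 86.5% when a 0 h peak had to be in both libraries, 84.6% without 0 h replicate 2, 41.8% with maxima within 200 bp, 22.6% in the better-scoring 50%, and 48.2% to 86.7% with 1 replicate. For WRKY33 the share was 99.8% with 0 h peaks in both libraries, 97.3% in the better-scoring 50% and 99.4% to 99.6% with 1 replicate. For WRKY40 it was 100%, 98.3% and 99.5% to 100.0%.

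Promoter shares were 34.8%, 41.5% and 33.8% within 500 bp and 66.2%, 71.1% and 65.3% within 2000 bp, by construction.

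Sites of 1 factor only numbered 161, 507 and 329 when only reproducible sites of the other lines excluded them, 1, 68 and 2 in the better-scoring 50%, and 192 to 266, 631 to 972 and 339 to 461 with 1 replicate. At equal lengths WRKY40 had 21. WRKY33 had the most in each of these.

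Between 9 and 14 gene lists were called in every alternative. Of the single list results, 216 kept their side of the threshold, 13 lost it (abscisic acid for WRKY18 and jasmonate for WRKY33 most often) and 11 passed it, 10 of these with 1 replicate left out; the cause was not tested. Of 162 checks of named sites, 144 still found the site and 18 did not, for example WRKY18 at its own locus with maxima within 200 bp.

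Not run without a genome sequence: all W-box alternatives, targets by gene body, and a background from shifted sites. In the 2 h lists of replicate 2, the weakest tercile overlapped replicate 1 least, so statements on weak sites are the least precise; the role of depth was not tested, since library totals were not used here.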

Other observations

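The gene families below were tested only after the target lists were seen.

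All 3 factors bound near cell-surface receptor families, and near a family of ubiquitin ligases, that none of the fixed lists cover as families. Of 54 receptor-like protein genes (RLP), WRKY18 bound 12, WRKY33 9 and WRKY40 16, where rotated targets gave 1.87, 1.64 and 2.13 (permutation test by rotation, adjusted p = 0.000513, 0.00192 and 0.000385). RLP9, RLP20 and RLP21 were bound by all 3. Of 40 genes with the symbol prefix CRK, that of cysteine-rich receptor-like kinases, 12, 11 and 11 were bound (permutation adjusted p = 0.00231, 0.00192 and 0.0055), with CRK11, CRK14, CRK10, CRK3 and CRK28 bound by all 3. Whether each of them encodes such a kinase was not checked. Of 13 wall-associated kinase genes (WAK and WAKL), 5, 4 and 5 were bound, among them WAKL10, WAKL2, WAKL4 and WAKL5 by all 3 (permutation adjusted p = 0.0133, 0.0423 and 0.0194). Of 22 U-box ubiquitin ligase genes (PUB), 5, 7 and 8 were bound, with PUB12, PUB17 and PUB24 bound by all 3 (permutation adjusted p = 0.0136, 0.00077 and 0.000385). PUB12 and PUB24 belong to the pattern receptor list of the report as well. So do PUB22 and PUB23, bound by WRKY33 and WRKY40, and the PUB result therefore repeats part of that list.

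Families were genes with 1 symbol prefix and at least 10 members, 154 in all, tested with 100000 rotations of the targets along the gene order and Benjamini-Hochberg adjustment within each line; 11 were called for WRKY18, 8 for WRKY33 and 11 for WRKY40, and 6 in all 3 lines. The MYB family, with 13, 11 and 13 of 116 bound, was a further one of these 6, as were the WRKY genes. The MAPKKK family was called for WRKY40 only, with 5 of 13 genes bound (MAPKKK5, MAPKKK13, MAPKKK14, MAPKKK15 and MAPKKK16, permutation adjusted p = 0.00308), against 3 for WRKY18 (0.0973) and 3 for WRKY33 (0.106), and the difference was not tested. Members of RLP and CRK often lie side by side, so 1 site can be near several members. The rotation keeps the order of genes but does not correct for long upstream regions. Members were not checked beyond their symbol, and 1 prefix can hold genes of different kinds. The symbol ACA1, for example, stood for more than 1 locus. The genes named here were chosen after their values were seen.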
